A study of Homo sapiens with 6 samples.

How the data were processed

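RNA was measured by strand-specific total RNA sequencing in 6 libraries of 2 established human uveal melanoma cell lines, 92.1 and Mel202, both engineered to deplete BAP1 when doxycycline is added. The labels give 2 uninduced and 2 induced libraries of 92.1, and 1 uninduced and 1 induced library of Mel202. Induced cells had 5 days of doxycycline, per the labels. The design text also speaks of primary tumours and of 2 replicates per condition, and these further samples were not analysed here. Nothing in the labels says that the replicates of 92.1 came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The labels describe no doxycycline-treated cells without the knockdown construct, so the effect of the drug and that of BAP1 loss were applied together in each comparison.

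Per the labels' protocols, the libraries were made with a stranded total RNA kit after removal of ribosomal RNA. The submitters' processing notes name FastQC, the aligner STAR and the human genome build hg19, without versions. The gene annotation used by the authors is not given in the sources used here. The deposited files hold whole-number read counts per gene, which the authors left unnormalized, in 3 columns for unstranded, same-strand and opposite-strand counting, per the layout of STAR's gene count output. The opposite-strand column held 96.4% to 96.9% of the gene reads of both stranded columns in each library and was used throughout. The rows for reads that were unmapped, multimapped, outside genes or ambiguous made up 32.1% to 41.4% of the reads of a library and were left out of library sizes and tests. Reads that map to several places are not counted by this method, so genes with near-identical copies, such as ribosomal protein, histone and HLA genes, carry uncertain counts.

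The files list 57820 gene identifiers, of which 51996 matched a symbol in a table of gene names. Gene type, longest transcript length and GC content came from GENCODE release 29, which belongs to another genome build than the files, so its coordinates were not used. Gene reads per library ranged from 23369941 to 43079377. MT-RNR2, the mitochondrial 16S ribosomal RNA, took 14.7% to 23.5% of them. Replicates were compared before they were averaged. A chi-square statistic over genes divided by its degrees of freedom was 234 for the 92.1 uninduced pair and 41.2 for the induced pair, far above sampling noise, so the libraries of each of these pairs were not copies of one another. The biological coefficient of variation was 0.407 in the uninduced pair and 0.199 in the induced pair.

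Levels are CPM, the reads of a gene scaled to a common library total, computed here from the deposited counts and scaled with trimmed mean of M-values (TMM) factors. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and with Benjamini-Hochberg adjustment at 0.05. The 4 libraries of 92.1 were tested alone. All 6 libraries were tested with the cell line as a covariate, and the difference between the responses of the lines was tested as an interaction. Mel202 has 1 library per arm, so in the interaction it was assumed to vary as 92.1 did, and its own comparison is a ratio of 2 libraries with 0.5 reads added and a 95% exact binomial counting interval. Such intervals cover counting error only.

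A total of 29 gene lists were fixed before the data were examined. They cover pigment cells, the 12-gene uveal melanoma classifier, neural crest, axon guidance, HOX genes, chromatin and DNA methylation factors, cell cycle, stress, signalling and differentiation programmes, ribosomal proteins, histones, and markers of other cell types. Of 856 listed entries, 838 were found in the files. Lists were tested on log2 CPM (prior count 2) with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists. With an estimated correlation, camera uses the few residual degrees of freedom of the fit, so a list can lose its call for that reason alone. In Mel202 each list's median was placed among 10000 random lists of the same size matched on mean expression.

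The rule for named genes, also set before the data were examined, took BAP1, PRAME, EZH2, DNMT1, DNMT3A, DNMT3B, TET1, TET2, TET3 and the classifier genes whatever their p. It added the 10 largest changes each way past adjusted p 0.05 among protein-coding genes with a mean of at least 5 CPM and no overlap between the 92.1 arms, up to 4 called members of each list, and the 5 largest Mel202 ratios each way among genes with at least 200 reads. No gene passed 0.05, so the same rule was applied at an adjusted p of 0.10, and up to 4 members of each list past a test adjusted over the list alone were named too. Both extensions were chosen after the values were seen, as was the use of 0.10 for the share of 92.1 genes with the same sign in Mel202.

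Alternatives were DESeq2 1.42.0, limma-voom, robust dispersion, other scaling factors, library totals, no filter beyond 1 read, a filter of 50 reads, unstranded counts, removal of mitochondrial genes, the replicate number as a block, all 6 libraries in 4 groups, and leaving out each library. The tests were run on simulated counts with 200 changed genes in each of 5 simulations, drawn from the real means. Over 17049 genes in the 92.1 design, 15.5% of genes changed by a fold of 2, 85.4% by 4 and 99.1% by 8 were recovered at 0.05. Over 19211 genes in the difference between lines, the shares were 0.896%, 14.0% and 59.1%. The model across both lines recovered 30.1%, 96.4% and 99.7%. The simulated counts took the trended dispersion in both arms, with no spread of genes around it. Changes were planted only in genes with many reads. The real arms of 92.1 differed in spread, so these shares are no measure of power in the real data. A lack of calls therefore does not exclude changes by a fold of 4 or 8.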

Results

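The series measured gene expression in 2 uveal melanoma lines before and after induced depletion of BAP1, a nuclear deubiquitinase that removes ubiquitin from histone H2A and is lost in aggressive uveal melanomas. The 92.1 line had 2 uninduced and 2 induced libraries, and Mel202 had 1 of each. Gene reads numbered 34913049 and 41465028 in the uninduced 92.1 libraries, 34408268 and 43079377 in the induced ones, and 23369941 and 25234825 in uninduced and induced Mel202.

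BAP1 itself (ENSG00000163930.5) was lower in each induced library, as the labels state. It stood at 75.0 and 58.5 CPM in uninduced 92.1 and at 18.3 and 17.8 CPM after induction, a level 3.76 times lower (log2 fold change -1.91, SE 0.23, n = 2 per arm). Its adjusted p was 0.0581 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In Mel202 it went from 69.6 to 10.1 CPM, a log2 ratio of -2.78 (95% counting interval -2.99 to -2.59). The plot of BAP1 levels shows the 6 libraries.

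**Figure D1:**
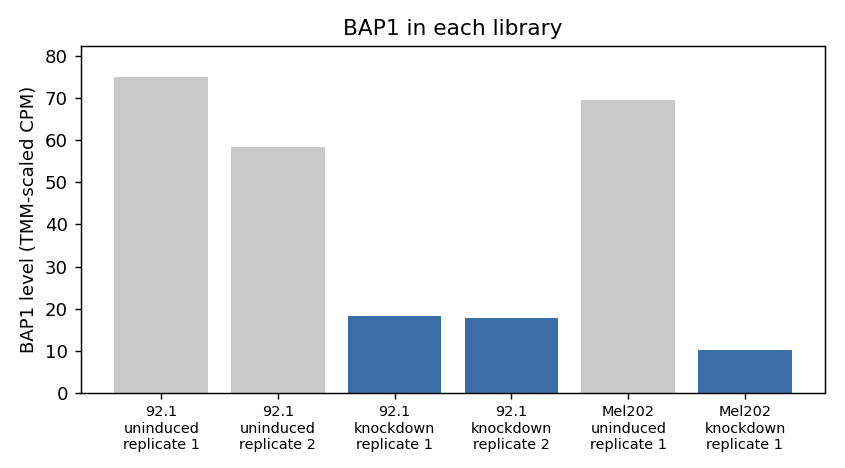
BAP1 level in each of the 6 libraries, in TMM-scaled CPM on a linear axis from 0. Grey bars are uninduced libraries, between 58.5 and 75.0 CPM, and blue bars are induced libraries, between 10.1 and 18.3 CPM.

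The first comparison asked which genes responded to induced BAP1 depletion in 92.1. Targets of the tumour suppressor p53 stood out. All 26 measured members were higher after induction, with a median log2 fold change of 1.27, and 18 of them rose in the edgeR test adjusted over the list alone. CDKN1A, an inhibitor of cyclin-dependent kinases, went from 66.6 and 73.6 CPM to 811 and 862 CPM (log2 fold change 3.55, SE 0.26). SESN1, a stress-induced inhibitor of growth signalling, rose by 2.70 (SE 0.23) on the log2 scale, the death receptor gene FAS by 2.86 (SE 0.30), and EDA2R, a receptor of the tumour necrosis factor family, by 2.20 (SE 0.25). The list was called by camera with a preset correlation (adjusted p = 3.14e-11) and not with an estimated correlation (adjusted p = 0.428). Its estimated correlation was -0.00934, below the preset one, so correlation among the members does not explain the lost call. The unadjusted camera p with the estimated correlation was 0.0159.

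No single gene passed an adjusted p of 0.05 among the 17049 tested with edgeR. At an unadjusted p under 0.05 the same test counted 4281 genes, and at an adjusted p under 0.10 it counted 592 higher and 893 lower, the smallest adjusted p being 0.0581. DESeq2 called 2076 genes and limma-voom 0 at 0.05. With library totals in place of TMM, edgeR called 84 genes higher and 256 lower at 0.05 and 480 higher and 1322 lower at 0.10, on a scale where the median of all genes lay at -0.16 in place of -0.03. The count at 0.05 was 4790 without uninduced replicate 1, 3988 without uninduced replicate 2, 1 without induced replicate 1 and 12 without induced replicate 2, the lone library of the arm being assumed to vary like the other pair.

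The largest rises among the 592 higher genes at an adjusted p under 0.10 were taken by the rule for named genes. PTCHD4, a Patched-domain membrane protein, had 3 reads in each uninduced library and went from 0.0762 and 0.0705 CPM to 18.3 and 11.3 CPM. The cytokine gene IL24 went from 0.178 and 0.282 CPM to 15.4 and 5.01 CPM, and LIF, another cytokine, from 0.381 and 1.62 CPM to 12.9 and 13.8 CPM. JAG1, a Notch ligand, went from 2.56 and 1.25 CPM to 35.8 and 32.2 CPM (log2 fold change 4.14, SE 0.41, adjusted p = 0.0581 in edgeR). The actin-binding protein gene TAGLN and smooth muscle actin ACTA2 had log2 fold changes of 4.67 (SE 0.66) and 3.95 (SE 0.52). NCKAP5, DCAF4L1 and the integrin gene ITGB8, also taken by the rule, had log2 fold changes of 4.49 (SE 0.89), 3.22 (SE 0.54) and 3.21 (SE 0.72). With a library left out, the log2 fold changes ranged between the fits without uninduced replicate 2 (lowest) and uninduced replicate 1 (highest) for JAG1 (3.71 to 4.74), DCAF4L1 (2.70 to 4.00) and ITGB8 (2.48 to 4.72). They ranged between those without uninduced replicate 1 (lowest) and uninduced replicate 2 (highest) for TAGLN (4.09 to 5.71), ACTA2 (3.41 to 4.84) and LIF (3.01 to 5.11, with 3.69 in the full fit). Without induced replicate 1 the lowest values were 3.43 for NCKAP5 and 4.40 for IL24, against highest values of 6.01 without uninduced replicate 1 and 6.03 without induced replicate 2.

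Among the genes with the largest falls at an adjusted p under 0.10, the extracellular matrix genes FREM1 and FREM2 had log2 fold changes of -4.59 (SE 0.42) and -3.25 (SE 0.42). The carbonic anhydrase gene CA14 went from 81.5 and 207 CPM to 5.09 and 12.2 CPM. BEST1, a chloride channel gene of the retinal pigment epithelium, went from 19.5 and 93.7 CPM to 3.18 and 3.89 CPM. The lipid transporter gene ABCA3 went from 6.52 and 36.9 CPM to 1.20 and 1.13 CPM, and the protease gene CTSV from 22.3 and 3.76 CPM to 0.599 and 1.25 CPM. RAB15 (-3.65, SE 0.34), the ganglioside synthase gene B4GALNT1 (-3.50, SE 0.52), ETNK2 (-3.39, SE 0.33) and PGGHG (-3.35, SE 0.71) were also taken by the rule, as log2 fold changes. In the full fit the log2 fold changes were -4.26 for ABCA3, -4.04 for BEST1, -4.10 for CA14 and -3.82 for CTSV. The smallest falls came without uninduced replicate 2 for ABCA3 (-2.50), BEST1 (-2.47), CA14 (-3.25) and PGGHG (-2.14), and the largest without uninduced replicate 1 for ABCA3 (-5.02), BEST1 (-4.75) and PGGHG (-3.98) and without induced replicate 2 for CA14 (-4.84). Without uninduced replicate 1 and uninduced replicate 2 in turn, CTSV was -2.04 and -4.58, B4GALNT1 -2.75 and -3.98, and FREM2 -2.63 and -3.68.

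Genes of cell division were lower in the induced 92.1 libraries, but mainly against uninduced replicate 1, since the 2 uninduced libraries differed widely. Which of these 2 was atypical cannot be told, as uninduced replicate 2 stood apart in genes of the ATF4 stress response. Of 53 measured G2 and M phase genes, 50 were lower (median log2 fold change -1.59), as were 40 of 45 S phase genes (-0.88) and all 14 replication-dependent histone genes (-1.54). No member of the 3 lists passed the edgeR test adjusted over its list alone. MKI67, a proliferation marker singled out after its values were seen, stood at 240 CPM in uninduced replicate 1, at 12.2 CPM in uninduced replicate 2 and at 29.5 and 46.6 CPM after induction. Without uninduced replicate 1 the medians were -0.08 for G2 and M phase, 0.17 for S phase and -0.50 for histones, and camera called none of the 3. With all libraries, camera at the preset correlation gave adjusted p = 0.00017, 0.00894 and 0.000964 for the 3 lists, and adjusted p = 0.822 for each with an estimated correlation. Without induced replicate 1 the S phase adjusted p was 0.0815 at the preset correlation.

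Cytosolic ribosomal protein genes were higher in 75 of 76 cases, with a median log2 fold change of 0.63, although none passed the edgeR test adjusted over the list alone. RPL39 and RPS27, singled out after their values were seen, had log2 fold changes of 0.96 (SE 0.33) and 0.59 (SE 0.30). The median was 0.39 without uninduced replicate 1 and 0.96 without uninduced replicate 2. Targets of the Hippo pathway coactivators YAP and TAZ were higher in 19 of 25 cases (median 0.40), and 3 rose over the list alone. These were the growth factor gene TGFB2 (log2 fold change 2.83, SE 0.43), RND3 (1.85, SE 0.41) and MYOF (1.88, SE 0.42). Camera with a preset correlation called ribosomal proteins (adjusted p = 3.14e-11) and YAP and TAZ targets (adjusted p = 0.0107), each with adjusted p = 0.822 with an estimated correlation. The plot of gene lists in the 92.1 libraries gives the 4 libraries for these groups.

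**Figure D2:**
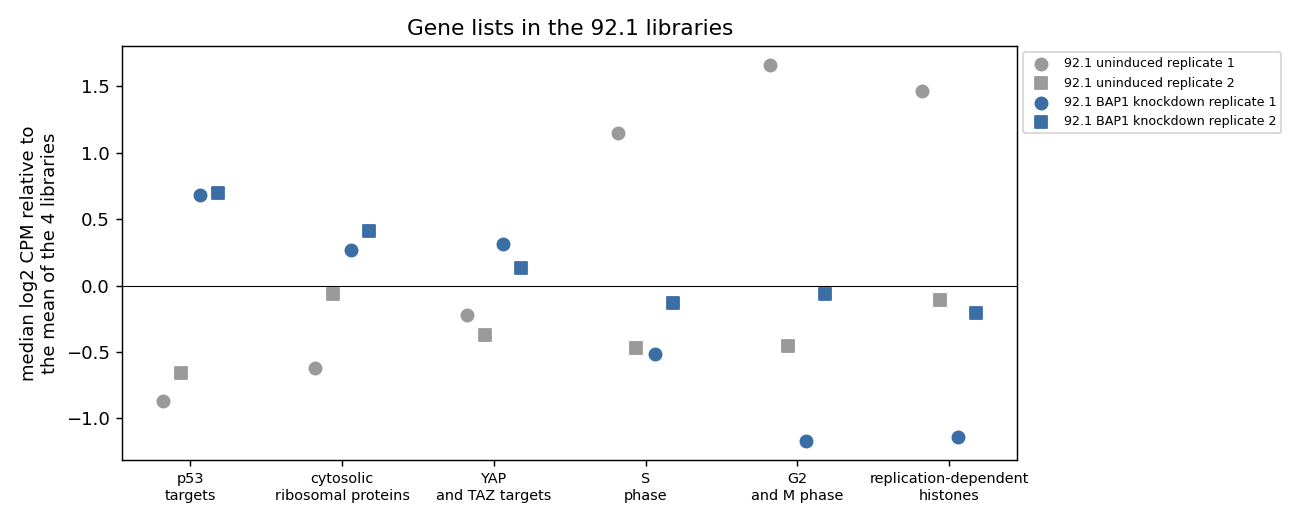
Median log2 CPM of the members of 6 gene lists in each 92.1 library, relative to each gene's mean over the 4 libraries, with uninduced libraries in grey, induced libraries in blue, circles for replicate 1 and squares for replicate 2. p53 targets lie at -0.87 and -0.66 in the uninduced and at 0.68 and 0.69 in the induced libraries, while G2 and M phase genes lie at 1.66 in uninduced replicate 1 and at -0.46 in uninduced replicate 2.

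Several lists held members that moved in opposite directions in 92.1. Of 20 neural crest genes, the endothelin receptor gene EDNRB rose by 2.50 (SE 0.24) on the log2 scale, the transcription factor genes PAX3 by 1.41 (SE 0.30) and TFAP2A by 1.12 (SE 0.23), and HAND2 fell by 1.89 (SE 0.48), each over the list alone. Of 60 axon guidance genes, 3 rose and 6 fell over the list alone, with the cytoskeletal regulator DPYSL2 at -2.34 (SE 0.22), the semaphorin receptor PLXNC1 at -1.80 (SE 0.36), SEMA4F at -1.64 (SE 0.30) and the ephrin receptor EPHA2 at 1.20 (SE 0.21). Of 20 outputs of MAPK signalling, 3 rose and 3 fell, including PHLDA1 at 1.89 (SE 0.27) and the ETS factors ETV5 at -1.60 (SE 0.31) and ETV4 at -1.29 (SE 0.25). Of 30 mesenchymal genes, 5 rose and 2 fell, among the former INHBA, with 1 and 4 reads in the uninduced libraries against 5.63 and 1.87 CPM after induction. Of 27 HOX genes, HOXB2 rose by 2.05 (SE 0.35), and HOXC11 and HOXD1 fell by 1.92 (SE 0.39) and 2.64 (SE 0.62), the latter with a log2 fold change of -3.94 without induced replicate 2 and -1.96 without induced replicate 1.

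Of the chromatin and methylation genes, none of those named in advance passed a test in 92.1. Among list members named only after the values were seen, AEBP2, an accessory subunit of Polycomb complex 2, rose by 1.58 (SE 0.24) over the list alone, and MBD5, a partner of the BAP1 complex, by 1.47 (SE 0.28), out of 43 Polycomb and PR-DUB genes. None of 24 genes of DNA methylation passed over the list alone. DNMT1, the maintenance methyltransferase, stood at 213 and 76.0 CPM uninduced and 57.8 and 59.0 CPM induced (log2 fold change -1.32, SE 0.46, edgeR adjusted p = 0.158). The values were -0.46 (SE 0.25) for DNMT3A, -1.03 (SE 0.46) for DNMT3B, 0.01 (SE 0.24) for TET1, 0.84 (SE 0.32) for TET2 and 0.20 (SE 0.41) for TET3. EZH2 had a log2 fold change of -0.64 (SE 0.52). Without uninduced replicate 1 and uninduced replicate 2 in turn, the values were -0.41 and -1.88 for DNMT1, -0.25 and -1.54 for DNMT3B, 0.84 and -0.24 for TET3 and 0.44 and -1.25 for EZH2.

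The 12 classifier genes separate Class 1 from Class 2 uveal melanomas, where BAP1 is usually lost in the latter. Of the 4 that are higher in Class 2 tumours, ECM1, an extracellular matrix gene, rose by 2.10 (SE 0.37) over the list alone, while CDH1, which encodes E-cadherin, and RAB31 fell by 1.99 (SE 0.68) and 1.91 (SE 0.34). CDH1 was near the floor in 92.1, at 0.863 and 1.55 CPM uninduced and 0.150 and 0.456 CPM induced. HTR2B, a serotonin receptor gene, had a log2 fold change of -0.13 (SE 0.28). None of the 8 that are lower in Class 2 tumours passed over the list alone. Their log2 fold changes were 1.06 for LMCD1, 0.63 for ID2, 0.53 for EIF1B, 0.40 for FXR1, 0.38 for SATB1, 0.13 for ROBO1, -0.02 for MTUS1 and -0.40 for LTA4H. Without uninduced replicate 1 and uninduced replicate 2 in turn, the values were 1.91 and -0.0335 for ID2 and -0.0511 and 1.02 for SATB1, and CDH1 stood at -2.99 without induced replicate 2 and -1.42 without induced replicate 1. PRAME, a cancer-testis antigen gene, was near the floor in 92.1, at 1.07 and 2.33 CPM uninduced and 0.300 and 0.456 CPM induced, and its log2 fold change was -2.18, or -1.49 without uninduced replicate 2 and -2.63 without uninduced replicate 1.

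The remaining lists were not called by camera in 92.1. Pigment cell genes had a median log2 fold change of -0.34, with ACP5 alone falling over the list (-2.21, SE 0.30), and antigen presentation genes had -0.37, with the immunoproteasome gene PSMB9 alone falling (-2.80, SE 0.52). The medians were -0.43 for interferon-stimulated genes, -0.13 for hypoxia, -0.24 for cholesterol synthesis, 0.37 for immediate early and heat shock genes, -0.50 for secretory pathway stress, 0.02 for mitochondrially encoded mRNAs and -0.51 for epithelial genes. The stress response driven by ATF4 had a median of -0.74, which became 0.66 without uninduced replicate 2 and was then called higher (adjusted p = 0.00364), and -1.33 without uninduced replicate 1, when it was called lower (adjusted p = 1.66e-05). Cholesterol synthesis became 0.51 without uninduced replicate 1 (adjusted p = 0.0208). Fibroblast markers had a median of -0.23 and markers of retinal pigment epithelium and retina -0.27, the latter with BEST1 lower and RPE65 higher over the list alone, at no more than 0.300 CPM for RPE65. Too few endothelial markers were measured for a test in any comparison, and too few blood and immune markers in 92.1.

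The second comparison asked what changed in Mel202, from 1 library per arm and so with no replicate check. Here the S phase and G2 and M phase genes were higher after induction, in 40 of 45 and 46 of 53 cases. Their median log2 ratios of 0.80 and 0.59 lay above all 10000 matched random lists. Random lists hold unrelated genes, whereas members of these lists moved together, with estimated correlations of 0.970 and 0.926 in 92.1. Libraries of 1 label can therefore differ widely in them. Relative to the mean of the 92.1 libraries, the uninduced replicates stood at 1.14 and -0.47 for S phase and 1.66 and -0.46 for G2 and M phase. MCM5, part of the replicative helicase, went from 46.6 to 101 CPM and the cyclin gene CCNB1 from 65.2 to 145 CPM, both singled out after their values were seen. Antigen presentation genes had a median of -0.75, below all random lists, with HLA-B at 9.91 and 4.74 CPM and TAP1, a peptide transporter gene, at 17.6 and 6.63 CPM, also singled out afterwards. With 3 members at 0 reads in 1 or both libraries set to a floor of 3 reads, or left out where neither library exceeded it, that median was -0.65.

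p53 targets in Mel202 had a median log2 ratio of 0.28, at percentile 86.7 of matched random lists, with 17 members higher and 9 lower. CDKN1A went from 85.8 to 225 CPM (log2 ratio 1.39, interval 1.32 to 1.47), BTG2 from 12.9 to 24.4 CPM and TRIAP1 from 31.4 to 52.4 CPM, while SESN1 and EDA2R had ratios of -0.04 and 0.02. The classifier genes higher in Class 2 had a median of 0.97 (percentile 99.7), with ECM1 at 2.18 (interval 1.88 to 2.50) and CDH1 at 1.63 (interval 1.21 to 2.08). Histone genes (0.56, percentile 98.8), immediate early and heat shock genes (0.47, percentile 99.7), secretory stress (0.48, percentile 98.5) and hypoxia (0.42, percentile 99.2) also lay high. HOX genes had a median of -0.60 (percentile 1.97), or -1.0 with members at 0 reads treated by the same floor. Of their 32 members, 9 had an interval below 0 and 0 an interval above it. Pigment genes (-0.10, percentile 2.41), mitochondrial mRNAs (-0.18, percentile 1.32), axon guidance (-0.29, percentile 2.97) and ribosomal proteins (0.15, percentile 4.85) lay low among lists matched on expression. With the trend of ratios on transcript length removed, a step chosen after the values were seen, histone genes stood at 0.13 (percentile 27.1) and no longer lay high. Axon guidance then stood at -0.00477 (percentile 94.8), at the other end of the random lists, and ribosomal proteins turned to -0.0451. Mitochondrial mRNAs moved to -0.61 (percentile 0) and p53 targets to 0.36 (percentile 96.8).

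The other lists in Mel202 had median log2 ratios of -0.18 for the classifier genes lower in Class 2, 0.06 for neural crest, 0.01 for Polycomb and PR-DUB, 0.17 for DNA methylation, -0.28 for interferon-stimulated genes, 0.26 for ATF4, 0.12 for MAPK, 0.04 for YAP and TAZ, -0.11 for mesenchymal genes, 0.01 for epithelial genes and 0.19 for cholesterol synthesis. Matched random lists were not centred on 0, with medians of 0.18 for ATF4, 0.15 for cholesterol synthesis, 0.13 for DNA methylation and 0.10 for Polycomb and PR-DUB. Among their random lists these other lists lay between percentiles 10.2 and 74.7. With the same floor the mesenchymal and epithelial medians were -0.43 and -0.75. Markers of fibroblasts, blood and immune cells and retina rested on 4, 3 and 6 genes, with medians of -1.61, 2.16 and 0.01, or -1.64, 1.88 and -0.71 with the floor, and the leukocyte marker PTPRC reached no more than 1.42 CPM and the fibroblast marker COL1A1 no more than 0.129 CPM in Mel202. DNMT1 was higher at 0.81 (interval 0.72 to 0.91) and EZH2 at 0.55 (interval 0.41 to 0.69), whereas TET1 was lower at -1.16 (interval -1.27 to -1.06) and DNMT3A at -0.61 (interval -0.72 to -0.50). PRAME was abundant in this line, at 276 and 337 CPM. The ratios were 0.24 for DNMT3B, -0.55 for TET2, -0.24 for TET3, 0.31 for RAB31 and -0.01 for HTR2B. They were -1.58 for SATB1 and -0.73 for MTUS1. Of the 8 classifier genes lower in Class 2, 2 were higher and 6 lower, with intervals above 0 for 2 and below 0 for 4.

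The largest ratios in Mel202 were 4.75 for ACTL8, an actin-like testis gene, 3.82 for the bile acid conjugating enzyme BAAT, 3.26 for the receptor gene GPR158, 3.19 for LRRC4 and 2.81 for TNFRSF12A, the receptor of the cytokine TWEAK. The lowest were -4.75 for WDR72, -3.22 for the transcription factor KLF9, -3.14 for the scaffold gene AKAP9, -3.13 for the phospholipid flippase ATP8A1 and -3.03 for PLEKHH2. In 92.1, BAAT, GPR158 and TNFRSF12A had log2 fold changes of 4.28, 3.14 and 1.04, ATP8A1 and PLEKHH2 had -1.54 and -2.84, and AKAP9 had 1.12. Ratios in this line fell with transcript length, from a median of 0.30 in the group of genes with the shortest transcripts (median 1886 nucleotides) to -0.20 in that with the longest (median 7356 nucleotides). With the length trend removed, AKAP9 and ATP8A1 stood at -2.69 and -2.80.

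**Figure D3:**
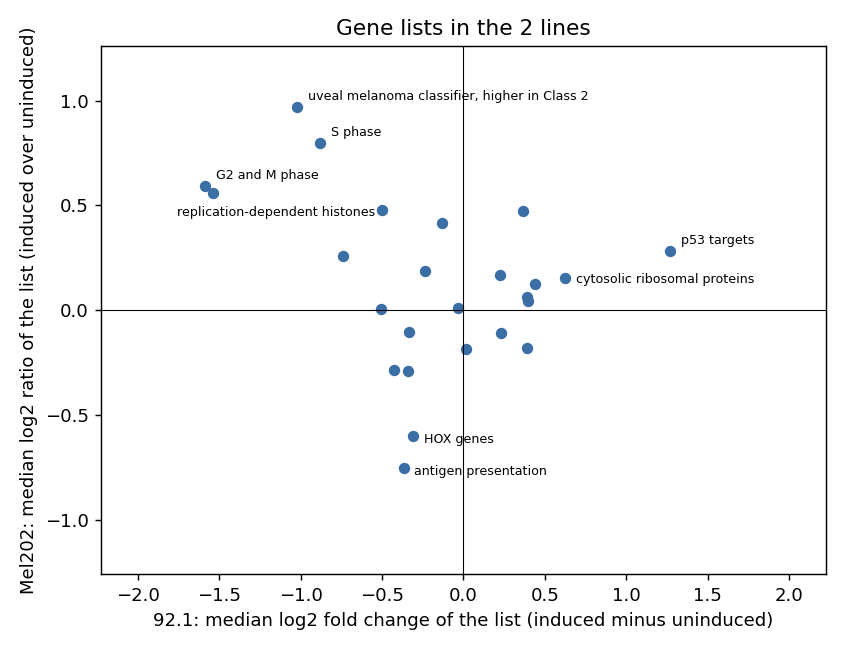
Median log2 change after induction of each gene list in 92.1 (horizontal axis) and Mel202 (vertical axis), 1 point per list, markers of other cell types left out. p53 targets lie at 1.27 and 0.28, and G2 and M phase genes at -1.59 and 0.59, where the 92.1 value rests on uninduced replicate 1.

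The third comparison fitted a common change over both lines, to which 92.1 gives 4 of the 6 libraries. p53 targets were higher in all 26 cases in this fit (median log2 fold change 1.03), against 17 of 26 in Mel202 on its own, and 17 rose over the list alone, among them CDKN1A (2.88, SE 0.46), BTG2 (2.06, SE 0.40), TRIAP1 (1.31, SE 0.25) and PLK3 (1.47, SE 0.30). ECM1 rose over its list at 2.14 (SE 0.31). HOX genes were lower in 26 of 32 cases (median -0.42), though HOXC11 alone fell over the list (-1.73, SE 0.35). Antigen presentation genes were lower in 20 of 26 cases (median -0.33), with PSMB9 alone falling over the list (-2.79, SE 0.47). Axon guidance genes had a median of -0.42, with 1 rising (EPHA4, with 0 and 1 reads in Mel202 and so a value from 92.1) and 5 falling over the list alone, among them SEMA4F (-1.59, SE 0.26), DPYSL2 (-1.79, SE 0.35) and EFNB3 (-1.58, SE 0.32).

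At an adjusted p under 0.10, edgeR counted 42 genes higher and 79 lower across both lines. The named genes that were higher were CDKN1A, ECM1, the tumour suppressor candidate BLCAP (1.39, SE 0.22), GFOD2 (1.37, SE 0.23), the cytidine deaminase APOBEC3C (1.34, SE 0.23), the glycosylation enzyme PMM2 (1.29, SE 0.24), the ribosome biogenesis factor NOL6 (1.24, SE 0.20) and the mitochondrial histidyl-tRNA synthetase HARS2 (1.18, SE 0.20). Lower were FREM1 (-4.28), RASSF4 (-3.10), PLEKHH2 (-2.88), the endoplasmic reticulum oxidase ERO1B (-2.84), EBF4 (-2.69), ANO9 (-2.51), RTN2 (-2.42), DOCK11 (-2.42), the actin bundler PLS1 (-2.35) and KYAT1 (-2.31). FREM1 and ANO9 had 6 or fewer reads per Mel202 library, so their values come from 92.1. Other members past a test over their list alone were ACP5 (-2.03), ETV5 (-1.45), DUSP4 (-0.89), COL6A2 (-1.47) and BEST1 (-3.17). INHBA and RPE65, with 0 reads in Mel202, also passed, on values that come from 92.1 alone. So did the monocyte marker CD14, with 2 reads in each Mel202 library and no more than 0.779 CPM in any library.

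No gene passed 0.05 with edgeR among 19211 across both lines, where 3710 had an unadjusted p under 0.05, DESeq2 called 1424 and limma-voom 0. The 121 genes at 0.10 became 574 with library totals (18.1% higher), 642 without 92.1 uninduced replicate 1, 1258 and 1144 without the uninduced and the induced Mel202 library, and 0 without 92.1 uninduced replicate 2 or either induced 92.1 library. Camera at the preset correlation called p53 targets (adjusted p = 4.67e-10), ribosomal proteins (median 0.50, adjusted p = 6.19e-11) and YAP and TAZ targets (median 0.44, adjusted p = 0.0216) higher, and HOX genes (adjusted p = 0.0018), G2 and M phase genes (median -0.85, adjusted p = 0.032) and antigen presentation (adjusted p = 0.035) lower. None was called with an estimated correlation. The adjusted p was then 0.796 for p53 targets, HOX genes and YAP and TAZ targets. It was 0.831 for ribosomal proteins and antigen presentation and 0.945 for G2 and M phase. For p53 targets the estimated correlation was 0.345 in this fit, above the preset 0.01, with an unadjusted camera p of 0.0966. Unlike in 92.1 alone, correlation among the members may thus contribute to the lost call here. The G2 and M phase median became 0.26 without 92.1 uninduced replicate 1 (adjusted p = 0.127) and -0.32 without induced replicate 1 (adjusted p = 0.65). YAP and TAZ targets lost the call without uninduced replicate 2 (adjusted p = 0.0681) and without induced replicate 1 (adjusted p = 0.0797), and antigen presentation without uninduced replicate 1 (adjusted p = 0.105) and induced replicate 1 (adjusted p = 0.0797). Axon guidance was the list that fry called, lower at adjusted p = 0.0146. Camera at the preset correlation did not call it in this fit (adjusted p = 0.0692), nor did fry in 92.1 alone (adjusted p = 0.111). Its Mel202 median of -0.29 became -0.00477 with the length trend removed, a step that was not applied to this fit.

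The sign of the response was compared between the lines. Of the 1485 genes at an adjusted p under 0.10 in 92.1, 67.7% had the same sign in Mel202, 65.0% of the higher and 69.4% of the lower ones. The share was 56.4% in the other genes, and 10000 draws of these matched on expression reached at most 61.3%. With RLE factors the shares were 55.1% of the higher and 73.2% of the lower genes, against 56.1% in the other genes. With library totals they were 49.0% and 77.8%, so the share among higher genes depended on scaling. A gene with no reads in either Mel202 library has a ratio set by scaling and the added reads alone. This ratio was slightly positive with TMM, so such genes counted as higher, and slightly negative with RLE factors. Such genes thus add to the 65.0% with TMM and to the 73.2% with RLE factors, and neither share is a clean measure. With genes limited to a mean of at least 5 CPM, a filter that need not remove all such genes, the shares were 63.8% of the higher and 67.4% of the lower genes. The other genes then had 55.3%, a share not split by direction. For all called genes the RLE share was 66.0%, against at most 61.0% in its random draws. Over 10591 genes with at least 5 CPM, the fold changes of the lines had a Pearson correlation of 0.19, across genes, which are not independent replicates. The correlation was 0.0604 without 92.1 uninduced replicate 2 and 0.279 without uninduced replicate 1. Without 92.1 uninduced replicate 2 the share was 54.9% of 5607 genes, against 51.7% in the genes not called in that fit and at most 54.0% in its random draws. It was 3 of 3 genes without induced replicate 1.

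No gene had a response that differed between the lines at an adjusted p of 0.05 in edgeR's interaction test, in which 1699 genes had an unadjusted p under 0.05. DESeq2 called 117 and limma-voom 0, and edgeR 927 without 92.1 uninduced replicate 1 and 1 without uninduced replicate 2. Of the p53 targets, 7 of 26 had a negative difference, Mel202 minus 92.1, over the list alone (median of the list -0.84). Camera called the list lower with a preset correlation (adjusted p = 2.88e-05) and not with an estimated correlation (adjusted p = 0.943). The estimated correlation was -0.0132, below the preset one as in 92.1 alone, with an unadjusted camera p of 0.0348.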

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

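The tests weighed here for p53 targets were all chosen only after the result was seen. The lowest p53 target median among the fits without 1 library was 1.19, so no single 92.1 library sets the rise. With library totals in place of TMM the median was 1.12, which speaks against scaling as the cause. Doxycycline or the hairpin itself remains possible, since none of the 6 libraries is an induced one without the hairpin, and the median in Mel202 was 0.28.

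The tests weighed here for cell division genes were likewise chosen only after the result was seen. The G2 and M phase median was -0.0825 without 92.1 uninduced replicate 1, so the fall seen with all libraries rested on that library. Uninduced replicate 2 was then the only control, and it stood apart as well. Its median for the ATF4 stress response was 1.14, against -0.90 in uninduced replicate 1 and 0.22 and -0.51 in the induced libraries. These data cannot tell which of the 2 uninduced libraries was atypical. An exchange of labels is unlikely, because BAP1 in that library was 4.10 times its level in the higher induced 92.1 library. In Mel202 the median was 0.59, from 1 library per arm, which leaves open whether BAP1 loss acts on these genes at all. A difference in growth state between the uninduced cultures might explain MKI67 and TOP2A, but the labels hold no record of it.

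Of the tests weighed here for transcript length in Mel202, that of differences between libraries of 1 group was chosen only after the result was seen, and those of GC content and of a shared effect were set before. Log2 ratios in Mel202 had a rank correlation of -0.312 with transcript length over 10639 genes. Given GC content it was -0.244, and the closest of the 92.1 pairs of an induced and an uninduced library had -0.0203. The Mel202 ratios also had a rank correlation of 0.313 with GC content itself, which removal of the length trend did not address. The induced libraries of 92.1, which share a label, differed from each other with a correlation with transcript length of 0.285. The uninduced libraries of 92.1, which also share a label, had -0.000826. The trend may therefore come from library preparation, and it could inflate the low ratios of long genes such as AKAP9.

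The 6 libraries can be divided into 2 groups of 3 in 10 ways, too few for a small share, and this check was chosen after the results were seen. The true division gave 3710 genes with an unadjusted p under 0.05 across both lines, against at most 1780 in any other, and was the only 1 of the 10 to reach that number. For p53 targets past the test over the list alone it gave 17, against at most 2 elsewhere, again 1 of 10. By camera at the preset correlation, p53 targets passed an adjusted p of 0.05 in 5 of the 9 other divisions, down to 2.74e-08. These 5 keep part or all of the contrast within 92.1 and are no null. The division that exchanged only the Mel202 libraries gave 1750 genes and 0 p53 targets over the list alone. The lead of the true division in these counts thus also rests on the single Mel202 pair. In the 4 divisions with 1 uninduced and 1 induced 92.1 library on each side, the adjusted p ranged from 0.161 to 0.571. For the number of gene lists called by camera it gave 6, which 9 of the 10 divisions reached, with up to 11, and the same 4 divisions gave 7 to 11, so the number of lists called at the preset correlation does not set the true division apart.

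The responses of the lines differed for 7 lists in camera at the preset correlation, a test chosen after the values were seen, and for 0 with an estimated correlation (adjusted p = 0.943) or with fry. As Mel202 minus 92.1, the median differences were 2.20 for G2 and M phase, 1.52 for S phase, 1.95 for histones, 0.85 for secretory pathway stress, -0.84 for p53 targets, -0.53 for ribosomal proteins and -0.42 for mesenchymal genes. Without 92.1 uninduced replicate 1 they were 0.86, 0.58 and 0.99 for G2 and M phase, S phase and histones, -0.29 for ribosomal proteins and -0.86 for mesenchymal genes, and the G2 and M phase difference lost its call (adjusted p = 0.104). Without uninduced replicate 2 the differences were 2.79, 2.16 and 2.61 for G2 and M phase, S phase and histones and -0.86 for ribosomal proteins, and mesenchymal genes lost their call (-0.31, adjusted p = 0.257). Mesenchymal genes stood at -0.24 without induced replicate 1, and secretory stress lost its call without induced replicate 2 (adjusted p = 0.0534). Outside the p53 targets, single members, named after their values were seen, differed over their list alone in both directions. TAGLN (-7.16, SE 1.34) had a log2 ratio of -2.32 in Mel202 (interval -4.91 to -0.71, from 17 and 3 reads), opposite to its rise in 92.1, and ACTA2 (-4.11, SE 0.83), DSP (-5.09, SE 1.09), FOSB (-4.62, SE 0.76), EDNRB (-2.52, SE 0.44) and PHLDA1 (-2.42, SE 0.45) also had negative differences. The classifier genes CDH1 (3.59, SE 1.04), near the floor in 92.1, and RAB31 (2.20, SE 0.59) had positive ones.

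The same-strand column, which holds at most 3.61% of the stranded gene reads, was tested in 92.1 after the main values were seen. edgeR called 101 of 7585 genes, 50 higher and 51 lower, and DESeq2 286. Of the 101, 51 had a value in the main column, 31 with the same sign. PCSK7 had a log2 fold change of 5.34 (SE 0.53) there against 0.45 in the main column, and A1CF had 4.42 (SE 0.46). Reads in this column can come from a neighbouring gene on the other strand, as for ACTA2-AS1 (3.76, SE 0.45), which lies opposite the rising ACTA2.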

How the results depend on the processing

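The gene counts moved most. In 92.1 the 0 genes at adjusted p 0.05 became 2076 with DESeq2, 340 with library totals, 3124 with no filter beyond 1 read, and 1 to 4790 when a library was left out; the 1485 at 0.10 became 2869 with DESeq2, 3955 with no filter and 3 to 6450. Across both lines the 0 genes at 0.05 became 1424 with DESeq2, 1884 with no filter and 5 with unstranded counts; the 121 at 0.10 became 2123 with DESeq2, 215 with RLE factors, 574 with library totals, 2591 with no filter, 0 with a filter of 50 reads, 241 with unstranded counts, 199 with robust dispersion, 222 without mitochondrial genes, and 0 to 1258 when a library was left out. The 0 genes that differ between lines at 0.05 became 117 with DESeq2, 575 with no filter and 0 to 927, and those at 0.10 became 196, 766 and 0 to 1794. BAP1 in 92.1 was -1.91 with DESeq2, -2.05 with library totals and -2.07 to -1.73. The share with the same sign was 70.1% with library totals and 54.9% to 100%. Lists called numbered 0 with an estimated correlation and with fry in 92.1, and 0 and 1 across both lines; they were 6 to 11 and 4 to 10 when a library was left out. The cause was not tested.

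Replicate numbers were used as a block, although the labels do not say that equal numbers belong together and the deviations of equal numbers correlated at -0.125 over 19211 genes. With the block 247 genes changed in 92.1 at 0.05, 44 across both lines at 0.10, and BAP1 was -1.90 (adjusted p = 0.0412 in edgeR). Crossing the numbers gave 1373 genes at 0.05 and 2678 at 0.10 in 92.1. Cholesterol synthesis across both lines turned to 0.0661 with the block and 0.0554 with crossed numbers.

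Some signs turned. Mitochondrial mRNAs in 92.1 were -0.0864 with library totals and -0.0087 with unstranded counts, fibroblast markers 0.33 with no filter, hypoxia across both lines -0.0733 with library totals and -0.00224 with no filter, TET1 -0.13 with library totals and -0.0224 with unstranded counts, and MTUS1 0.00995 with unstranded counts and 0.000733 with all 6 libraries in 4 groups. When a library was left out, lists in 92.1 ranged from -0.64 to 0.0408 for pigment genes, -0.15 to 0.0600 for Polycomb, -1.46 to 0.17 for S phase, -1.33 to 0.66 for ATF4, -0.37 to 0.52 for mitochondrial mRNAs, -0.81 to 0.17 for epithelial genes, -0.27 to 0.0159 for hypoxia, -0.32 to 0.51 for cholesterol synthesis, -0.0227 to 0.44 for immediate early genes and -0.74 to 0.18 for fibroblast markers. Across both lines they ranged from -0.40 to 0.0852 for classifier genes higher in Class 2, -0.0386 to 0.0389 for Polycomb, -0.60 to 0.41 for S phase, -1.18 to 0.26 for G2 and M phase, -0.59 to 0.51 for ATF4, -0.35 to 0.14 for mitochondrial mRNAs, -0.21 to 0.26 for cholesterol synthesis and -0.13 to 0.11 for secretory stress. Camera called S phase higher across both lines without 92.1 uninduced replicate 1 (adjusted p = 0.000573), and ATF4 higher without uninduced replicate 2 (adjusted p = 0.00132) and lower without uninduced replicate 1 (adjusted p = 0.0231). Genes in 92.1 ranged from -1.25 to 0.44 for EZH2, -0.22 to 0.29 for TET1, -0.24 to 0.84 for TET3, -0.49 to 0.17 for HTR2B, -0.0335 to 1.91 for ID2, -0.73 to 0.0532 for LTA4H, -0.13 to 0.0949 for MTUS1, -0.17 to 0.40 for ROBO1 and -0.0511 to 1.02 for SATB1. Over single lists and genes, 1974 values stayed the same, 427 were stronger, 34 weaker, 15 moved and 47 reversed. A value with a p-value counted as the same if it kept its sign and its side of the threshold, whatever its size. Stronger and weaker there mean that the p-value crossed the threshold, not that the effect was larger or smaller.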

Other observations

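The lines differed from each other far more clearly than the induced from the uninduced cells. In the model across both lines, with the line term examined after the values were seen, edgeR called 1873 genes higher and 1491 lower in Mel202 at an adjusted p of 0.05. UBB, a polyubiquitin gene, stood at 268 and 369 CPM in Mel202 and at no more than 0.150 CPM in 92.1. DDIT4L, a stress-induced inhibitor of growth signalling, stood at 38.4 and 175 CPM in Mel202 and had 0 reads in 92.1. The imprinted gene MEST and the malic enzyme gene ME1 were also nearly confined to Mel202. Conversely, the calcium-binding protein gene S100A6 ranged from 18.6 to 36.2 CPM in 92.1 and had 0 reads in Mel202, as did the caveolae gene CAVIN1, B3GALNT1 and MYO3A.

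Camera at the preset correlation placed mitochondrial mRNAs (median -1.56, adjusted p = 0.000217), ribosomal proteins (-0.51, adjusted p = 0.000458) and antigen presentation (-0.71, adjusted p = 0.00934) lower in Mel202. It placed G2 and M phase genes (0.73, adjusted p = 0.0108) higher. Each list had adjusted p = 0.921 with an estimated correlation. Relative to the mean of the 92.1 libraries, G2 and M phase genes stood at 0.64 and 1.19 in Mel202, within the 92.1 range of -1.17 to 1.66. Ribosomal proteins also overlapped between the lines, at -0.62 and -0.46 against -0.62 to 0.41.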
